A study of Mus musculus with 20 samples.

How the data were processed

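The series holds 20 RNA-seq libraries from 10 male C57BL/6J mice. Each mouse gave trigeminal ganglia (TG) and nucleus accumbens (NAc), collected 24 h after the last injection of morphine or vehicle, so there were 4 groups of 5 libraries. Per the labels' protocols, RNA was isolated with TRIzol, purified on RNeasy columns and turned into strand-specific poly(A) libraries with an Illumina TruSeq kit. Sequencing ran for 101 cycles on an Illumina HiSeq. The sources conflict on the read type, since the design text says that both ends were read and the protocol says that 1 end was read. The protocol describes an earlier and a later set of sequencing lanes without saying which libraries ran on which, so no batch term could be fitted.

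The authors deposited expected counts, that is read counts estimated per RefSeq transcript, for 107185 transcripts. The counts were not normalised, and 56.7% of the values were not whole numbers. Per the submitters' processing notes, kallisto 0.43 was used with mouse build GRCm38. Its settings, the transcript index and the way lanes were pooled are not given in the sources used here. Estimated counts share reads between similar transcripts by a model, so genes with near-identical copies or many isoforms are less certain than their totals imply.

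Transcripts were summed per gene with the RefSeq annotation of GRCm38.p6, which matched 86631 transcripts (80.8%) holding 90.0% of the counts. Of these, 174 were matched only through the RefSeq table of GENCODE M21. The other 20554 transcripts were kept as unnamed features, so that library totals stayed whole, and 11998 transcripts had 0 in every library. Sums were rounded to whole numbers and gave 53516 features, 32962 of them named genes. No transcript encoded by the mitochondrial genome was among the features. Coordinates are those of whole genes in GRCm38.p6.

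Library totals ran from 61285916 to 76110288 counts in TG and from 52402037 to 64357778 in NAc. The unmatched share ran from 9.05% to 9.15% in TG and from 10.8% to 11.2% in NAc. Between replicate libraries the chi-square per gene, over genes with at least 20 counts per pair, lay between 6.37 and 169, where counting error alone gives about 1.

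Each treatment comparison was fitted on the 10 libraries of its tissue with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Features were filtered with filterByExpr, scaled with TMM factors, and fitted with estimateDisp and a robust glmQLFit. The interaction (effect in TG minus effect in NAc), the mean effect over both tissues, and the tissue difference in vehicle mice were fitted on all 20 libraries with 4 group means. All tests were 2-sided, p was adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Standard errors are the size of the log2 fold change divided by the root of the F statistic. CPM are counts scaled to a common library size with the TMM factors of the fit in question, so a gene's CPM differ slightly between the tissue fits and the fit on all libraries.

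Lists of genes for pathways, cell types and neighbouring tissues were fixed before the data were examined, as were the comparisons, tests, thresholds, most of the alternatives and the rule for the genes named. Of 44 lists, 43 in TG and 42 in NAc had the 3 measured members needed. The 1 list with no measured member was that of transcripts encoded by the mitochondrial genome. Lists were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01 and with an estimated correlation, and with fry, which asks whether the members move on balance in 1 direction. Adjustment was over the lists of a tissue.

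The rule names, for each treatment comparison and the interaction, up to 10 genes higher and 10 lower with the smallest p among those past the threshold, filled to 5 where fewer passed. It adds up to 4 members of each list, the opioid receptors and peptides, and a few markers of the clock, glucocorticoid response and immune cells. For the tissue difference it takes 5 genes in each direction with a mean of at least 50 CPM plus 4 markers, and for the mean effect 5 in each direction. Genes outside this rule are said to have been chosen after their values were seen.

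Because the TG and NAc libraries share mice, the mouse was tried as a block for the interaction and the tissue difference, and the replicate number for the other comparisons. The pairing comes from the mouse codes of the labels, and each mouse's deviations in TG and NAc had a correlation between -0.098 and 0.095. The share of each library that looked like the other tissue was estimated from genes at least 200 times higher in that tissue with at least 20 CPM, 41 genes for TG and 31 for NAc. This was chosen after the data had been seen.

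Alternatives were DESeq2 1.42.0, limma voom with quality weights, other scaling, other filters, single transcripts in place of sums, blocks, a looser threshold, and leaving out each library in turn. Named genes alone, a correction for GC content and length (mgcv 1.9.3), covariates for pituitary and cortical genes, and subtraction of the other tissue's share were added after the data had been seen. For each treatment result, 100 of the 126 splits of the mice into 2 groups of 5 were drawn, the real split included. For the tissue difference the 10 vehicle libraries of 5 mice were split in the same way, since a split of mice leaves the tissues as they are.

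The steps were tested on simulated data with 50 genes changed by each of 4 sizes. The changed genes were drawn from those with a mean over 1 CPM, so the shares recovered do not cover genes below that level. In TG, 30% of genes changed 1.25-fold, 56% of those changed 1.5-fold, 68% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 5.93% false calls. In NAc the shares were 6%, 34%, 56% and 90%, with 4.12% false calls. For the interaction they were 10%, 38%, 62% and 80%, with 4.04% false calls.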

Results

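RNA was measured in 2 tissues of the pathways of pain and reward. The trigeminal ganglia (TG) hold the cell bodies of the sensory neurons of the face and meninges, and the nucleus accumbens (NAc) is a part of the ventral striatum rich in opioid receptors and dopamine input. Of 10 mice, 5 received morphine and 5 vehicle, and both tissues were taken 24 h after the last injection, giving 4 groups of 5 libraries. The morphine mice carry the label OIH, in this field the abbreviation of opioid-induced hyperalgesia, a state in which opioid treatment itself raises sensitivity to pain. The comparisons ask which genes differ after morphine in each tissue and whether the tissues differ in that response. TG libraries held 61285916 to 76110288 estimated counts and NAc libraries 52402037 to 64357778.

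The tissues carried the transcripts their labels name. In vehicle mice, Scn10a, a sodium channel of nociceptors, averaged 791 ± 27.4 CPM in TG and 2.71 ± 0.956 CPM in NAc (SD, n = 5). The dopamine receptor genes lay the other way, with Drd1 at 0.764 ± 0.186 CPM in TG and 225 ± 82.1 CPM in NAc, and Drd2 lower in TG by a log2 fold change of -5.40 ± 0.26 (SE). The tetraspanin gene Cd9 (4.14 ± 0.04), the fatty acid elongase gene Elovl7 (3.26 ± 0.03), Msn (3.73 ± 0.04), which links actin to the membrane, Ostf1 (4.49 ± 0.05) and Arhgap28 (6.10 ± 0.07) were higher in TG with the smallest p. The glutamate receptor gene Gria1 (-5.22 ± 0.06), the neuronal adhesion gene Negr1 (-3.16 ± 0.03), Sema6b (-3.62 ± 0.05), Pnmal1 (-3.86 ± 0.06) and Tspoap1 (-3.02 ± 0.05) were lower. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 22232 of 32998 features differed, 10856 higher and 11376 lower in TG. Scaling by library size alone moved the median log2 fold change of all features from -0.06 to -0.21, with 9336 higher and 13228 lower.

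Clock genes rose in TG after morphine. Dbp, a transcription factor whose level follows the circadian clock (gene 13170, GRCm38.p6 chromosome 7, 45705100 to 45710203), rose from 16.0 ± 1.53 CPM in vehicle mice to 35.9 ± 3.79 CPM in morphine mice (SD, n = 5), a 2.24-fold difference. Ciart, which represses the clock's activators (gene 229599, chromosome 3, 95878500 to 95882257), rose from 1.75 ± 0.218 to 4.09 ± 0.379 CPM. The period genes Per3 (gene 18628, chromosome 4, 150997018 to 151044707), from 37.6 ± 2.66 to 58.4 ± 3.57 CPM, and Per2 (gene 18627, chromosome 1, 91415977 to 91459351), from 18.8 ± 2.07 to 31.3 ± 2.58 CPM, rose as well. Tef rose from 136 ± 4.22 to 170 ± 6.85 CPM and the cryptochrome gene Cry2 from 103 ± 2.68 to 120 ± 2.85 CPM. The list of clock genes driven through E-box elements by BMAL1 and CLOCK had 12 measured members, and all 12 were higher. Of these, 8 passed the threshold over all features tested (Dbp, Per3, Ciart, Tef, Cry2, Per2, Nr1d1 and Hlf), and 12 when adjusted over the list alone. The mean log2 fold change of the list was 0.535, with a camera adjusted p = 6.51e-27, adjusted p = 0.0035 with an estimated correlation and a fry adjusted p = 9.9e-06. Nr1d1 and Hlf, with Nr1d2, Bhlhe40, Bhlhe41 and Per1, are named here after their values were seen.

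**Figure D1:**
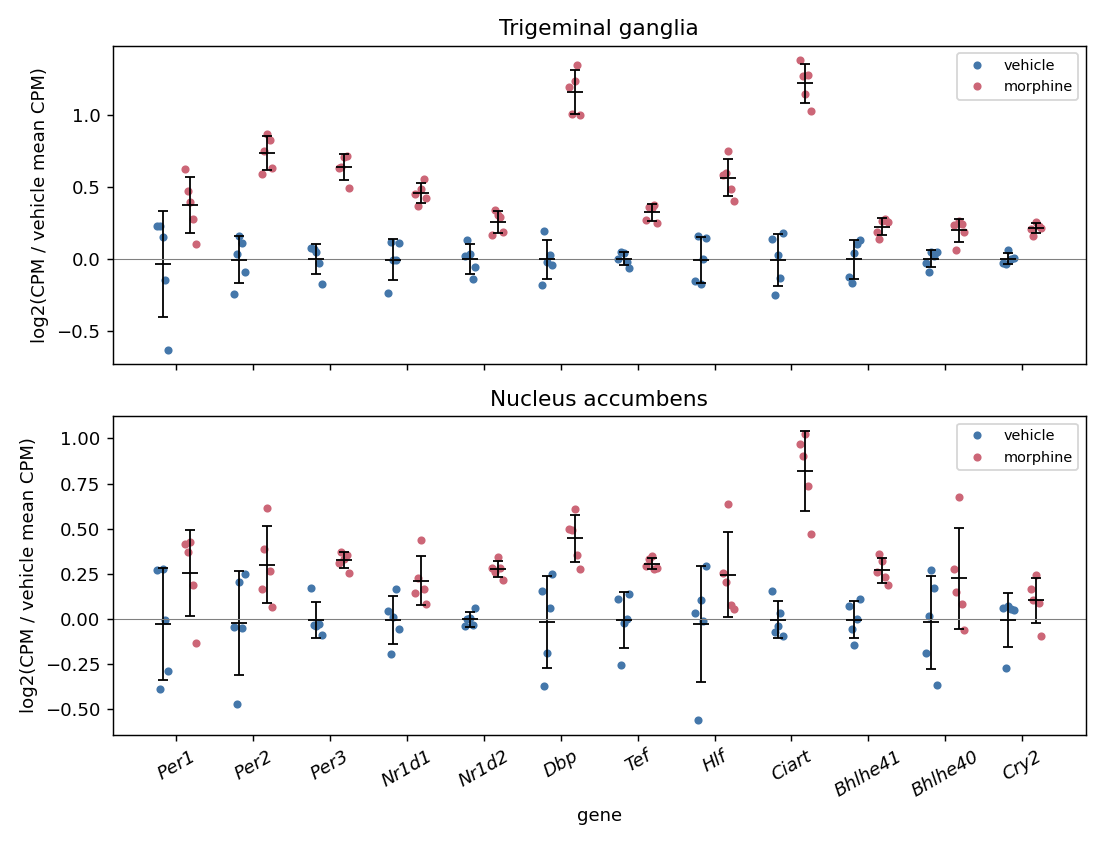
Each point is 1 library, drawn as log2 of its CPM over the mean CPM of the 5 vehicle libraries of that tissue, for the 12 genes of the E-box list; bars show the mean and SD of 5 libraries. In TG the morphine libraries of Dbp and Ciart lie above all vehicle libraries, with log2 fold changes of 1.16 and 1.23, and in NAc those of Dbp and Ciart are 0.45 and 0.83.

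The list of the clock's activator and night genes was not called in TG (8 members, camera adjusted p = 0.905). Its mean log2 fold change was -0.10, its median -0.03 and the direction of the test upward. Arntl, which encodes BMAL1, averaged 6.92 ± 1.30 CPM in vehicle mice and 3.90 ± 0.590 CPM in morphine mice (SD, n = 5), a log2 fold change of -0.83 ± 0.15 with an edgeR adjusted p = 0.0819. Adjusted over the list alone, 1 gene (Arntl) was lower and 1 (Cry1) higher, against 0 over all features tested.

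Outside the clock, Fabp7, the fatty acid-binding protein of satellite and other glia (gene 12140, chromosome 10, 57784923 to 57788450), fell from 186 ± 9.06 to 117 ± 10.1 CPM in TG. The genes for the lipoprotein lipase inhibitor Angptl4 (-0.73 ± 0.11), the polyamine acetyltransferase Sat1 (-0.43 ± 0.05), the endothelial GTPase Rhoj (-0.35 ± 0.05), Frmd6 (-0.17 ± 0.02) and Amotl1 (-0.13 ± 0.02) also fell, in log2 fold change ± SE. Tmod2, which caps actin filaments in neurons (gene 50876, chromosome 9, 75565621 to 75611342), rose by a log2 fold change of 0.24 ± 0.02. The protein kinase A anchor Akap11 (0.25 ± 0.03), the synaptic vesicle protein gene Dmxl2 (0.24 ± 0.03), the focal adhesion gene Tns2 (0.33 ± 0.04) and Thoc2l (0.93 ± 0.09) rose. Adjusted p of these 11 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 0.00345 and 0.0496.

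Several of the larger increases in TG were those of genes with long messages, which are named here after their values were seen. Lnpep, a membrane aminopeptidase, rose by a log2 fold change of 1.35 ± 0.16, the zinc finger genes Zfp292 by 1.62 ± 0.18 and Zbed6 by 1.58 ± 0.20, the phosphatase gene Ptpn4 by 1.15 ± 0.16 and the elongation complex gene Aff4 by 0.80 ± 0.11. The chromatin remodeller gene Atrx had 0 counts in the 5 vehicle libraries and 195 to 698 counts in the morphine libraries, at least 633-fold higher when the vehicle group is set to a floor of 3 counts. Its counts rest on 1 matched transcript, as do those of Lnpep and Zbed6, while other models of such genes can lie among the unmatched transcripts. For these genes the division of reads between isoform models is uncertain.

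In all, 53 of 29394 features passed the threshold in TG, 45 higher and 8 lower, against 709 in DESeq2 and 81 in limma voom. Of these, 45 were named genes, 38 higher and 7 lower, and 8 were unmatched transcripts. Scaling by library size alone gave 37 higher and 13 lower. The count was 30, 21, 24 and 24 without morphine replicate 1, 2, 3 or 5, and 25, 22, 33 and 21 without vehicle replicate 1, 3, 4 or 5 of TG. Leaving out 1 library ended the call of Amotl1 (each of the 10 libraries), Rhoj (all but morphine replicate 4), Frmd6 and Angptl4 (all but morphine replicate 4 and vehicle replicate 2), and Sat1 (morphine replicate 3 or 5, vehicle replicate 3 or 5), with adjusted p between 0.0503 and 0.138 where lost.

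Other gene groups moved by smaller or less even amounts in TG. Heat shock genes were lower, by a mean log2 fold change of -0.20, with 8 of 11 lower when adjusted over the list alone and 0 over all features, among them the chaperone genes Hspd1 (-0.15 ± 0.03), Hspa1b (-0.75 ± 0.18) and Hsph1 (-0.22 ± 0.05). The camera adjusted p was 1.2e-07, and adjusted p = 0.265 with an estimated correlation. MHC class II genes were lower by -0.305 (9 members, 3 lower adjusted over the list alone and 0 over all features: H2-Eb1, H2-Aa and H2-Ab1), with camera adjusted p = 0.0027 and adjusted p = 0.285 with an estimated correlation. MHC class I genes (-0.21, adjusted p = 0.658 with an estimated correlation), cytokines and NF-kB targets (-0.19, adjusted p = 0.149 with an estimated correlation) and interferon response genes (-0.16, adjusted p = 0.76 with an estimated correlation) were called lower by camera with adjusted p of 0.00274, 0.00717 and 0.0153. The mean of cytokines was -0.311 and -0.312 without morphine or vehicle replicate 3, and that of interferon genes -0.26 without morphine replicate 3. The interferon call was absent without morphine replicate 1, 2 or 4 or vehicle replicate 1, with means of -0.132, -0.061, -0.142 and -0.052 (camera adjusted p = 0.0765, 0.312, 0.0752 and 0.278).

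Glucocorticoid targets were higher in TG by a mean log2 fold change of 0.24. Adjusted over the list alone, 5 of 16 were higher and 1 lower, and 0 over all features. The lipid droplet gene Plin4 went from 5.81 ± 0.654 to 12.3 ± 4.09 CPM, Hif3a from 4.60 ± 1.23 to 7.24 ± 0.788 CPM and the receptor co-chaperone gene Fkbp5 from 55.3 ± 6.09 to 66.8 ± 4.78 CPM, whereas the cell cycle inhibitor Cdkn1a had a log2 fold change of -0.19 ± 0.05. The camera adjusted p was 0.00274, adjusted p = 0.43 with an estimated correlation, and 0.0533 without vehicle replicate 5. Genes of red blood cells were higher by 0.84 (camera adjusted p = 1.15e-04, adjusted p = 0.471 with an estimated correlation), 7 of 9 adjusted over the list alone and 0 over all features, including Slc4a1 (2.27 ± 0.70, or 1.36 without morphine replicate 3), Alas2 (1.16 ± 0.39) and Hba-a1 (0.93 ± 0.34).

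Lists for other tissues also moved with treatment in TG. Pituitary genes were higher by a mean log2 fold change of 1.20 (14 of 14 positive, 0 past the threshold), with camera adjusted p = 0.00274 and adjusted p = 0.742 with an estimated correlation, and by 0.789 without vehicle replicate 1. The growth hormone gene Gh, chosen after its values were seen, ran from 12.2 CPM in vehicle replicate 1 to 976 CPM in morphine replicate 3, with means of 257 ± 345 and 460 ± 444 CPM. With a pituitary score as a covariate, chosen after the data had been seen, 12 features passed in TG. The share of NAc transcripts in TG libraries was 0.369 ± 0.047% after morphine and 0.279 ± 0.045% after vehicle (SD, n = 5, exact permutation p = 0.0238, 2-sided). Beside it stand the higher lists of astrocytes (0.18, or 0.102 without morphine replicate 3, adjusted p = 0.602 with an estimated correlation, with Aldoc past the threshold adjusted over the list alone and 0 genes over all features) and of medium spiny neurons, the projection neurons of the striatum. Their direct pathway list (0.149, Ebf1 and Drd1) had adjusted p = 0.149 with an estimated correlation, their shared list (0.20, Gad2 and Gad1) adjusted p = 0.47, and each had 1 gene higher adjusted over the list alone and 0 over all features. The camera adjusted p of the 3 lists were 0.0027, 0.00512 and 0.0153, the last 0.065 without morphine replicate 5.

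No gene of opioid signalling or pain passed the threshold in TG. The mu receptor gene Oprm1 averaged 1.11 ± 0.149 CPM after vehicle and 1.82 ± 0.557 CPM after morphine (SD, n = 5; log2 fold change 0.71 ± 0.21, edgeR adjusted p = 0.263). The log2 fold changes of Oprd1 (-0.14 ± 0.05), Oprk1 (0.14 ± 0.10) and Pdyn (0.22 ± 0.18) did not pass either. The opioid list had a mean of 0.22, a median of -0.04 and a camera adjusted p = 0.931. Nociceptor genes were called lower by camera (mean -0.05, adjusted p = 0.023), with adjusted p = 0.742 with an estimated correlation. Adjusted over the list alone, P2rx3 (-0.19 ± 0.04) and Mrgprd (-0.19 ± 0.05) were lower and the sodium channel gene Scn9a (0.20 ± 0.04) higher, and over all features 0 passed in edgeR. This list lost its call without morphine replicate 2 or 3 or vehicle replicate 4 or 5 (adjusted p = 0.293, 0.0785, 0.114 and 0.0766). Calca, which encodes the migraine peptide CGRP, had a log2 fold change of -0.14 ± 0.08 and Cd74 of -0.22 ± 0.11. The lists of migraine peptides (adjusted p = 0.219), nerve injury genes (0.961) and immediate early genes (0.0642) were not called. For 11 of the 43 lists in TG and 5 of the 42 in NAc, none of them called, the mean, the median and the direction of the test differed in sign.

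In NAc no gene passed the threshold, but clock genes lay in the same direction as in TG. Ciart averaged 7.85 ± 0.560 CPM after vehicle and 14.0 ± 2.04 CPM after morphine (SD, n = 5; log2 fold change 0.83 ± 0.11, edgeR adjusted p = 0.126), and Nr1d2, a clock repressor, 175 ± 5.06 and 212 ± 6.51 CPM. Per3 (0.33 ± 0.05), Dbp (0.45 ± 0.12) and Per2 (0.31 ± 0.15) had positive values, and Arntl was at -0.20 ± 0.17. All 12 members of the E-box list were positive, 7 past the threshold adjusted over the list alone and 0 over all features. The mean was 0.327, with camera adjusted p = 6.23e-16, adjusted p = 0.137 with an estimated correlation and a fry adjusted p = 0.0167. Without vehicle replicate 2 the mean was 0.275 and without morphine replicate 3 0.281. Other genes with small p were Mme, the enkephalin-degrading peptidase (0.40 ± 0.08), and Atxn3 (0.22 ± 0.04).

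Genes of myelin and of its cells were lower in NAc after morphine. Mbp, a main protein of central myelin (gene 17196, chromosome 18, 82475091 to 82585637), averaged 2427 ± 126 CPM after vehicle and 2036 ± 72.8 CPM after morphine (SD, n = 5; log2 fold change -0.25 ± 0.05, edgeR adjusted p = 0.34). The iron carrier gene Trf (-0.34 ± 0.08), the myelin lipid enzyme gene Ugt8a (-0.37 ± 0.09) and Hapln2 (-0.33 ± 0.08) were lower too. All 14 oligodendrocyte genes were lower, 14 past the threshold adjusted over the list alone and 0 over all features. Their mean was -0.26, with camera adjusted p = 5.15e-18, adjusted p = 0.182 with an estimated correlation and a fry adjusted p = 0.0476. Oligodendrocyte precursor genes had a mean of -0.23, with Gpr17 at -0.37 ± 0.08, 1 lower adjusted over the list alone and 0 over all features, camera adjusted p = 6.12e-04 and adjusted p = 0.341 with an estimated correlation.

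Genes abundant in TG were also lower in the NAc of morphine mice. The peripheral myelin genes Pmp22, Gjb1 and Prx had log2 fold changes of -0.55 ± 0.09, -0.51 ± 0.08 and -0.78 ± 0.18. The Schwann cell list had a mean of -0.38, 6 of 13 lower adjusted over the list alone and 0 over all features, camera adjusted p = 7.63e-09 and adjusted p = 0.00734 with an estimated correlation. Nociceptor genes had a mean of -0.46, with 6 of 16 lower adjusted over the list alone and 0 over all features (among them Asic3, Scn11a, Piezo2 and Calca), camera adjusted p = 9.87e-05 and adjusted p = 0.341 with an estimated correlation. The satellite glia list (mean -0.15, camera adjusted p = 5.28e-05, adjusted p = 0.341 with an estimated correlation) had 1 gene, Sox10, lower adjusted over the list alone and 0 over all features. Avil, Prph and Pou4f1, markers of sensory neurons, had log2 fold changes of -0.94 ± 0.21, -1.16 ± 0.29 and -0.83 ± 0.23, the lowest of their list, which was not called (14 members, 9 negative, mean -0.20, median -0.02, camera adjusted p = 0.0592). Measured over 41 genes, the share of TG transcripts in NAc libraries was 0.196 ± 0.03% after morphine and 0.409 ± 0.107% after vehicle (SD, n = 5, exact permutation p = 0.0159, 2-sided). Vehicle replicate 5, at 0.223%, lay among the morphine libraries.

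**Figure D2:**
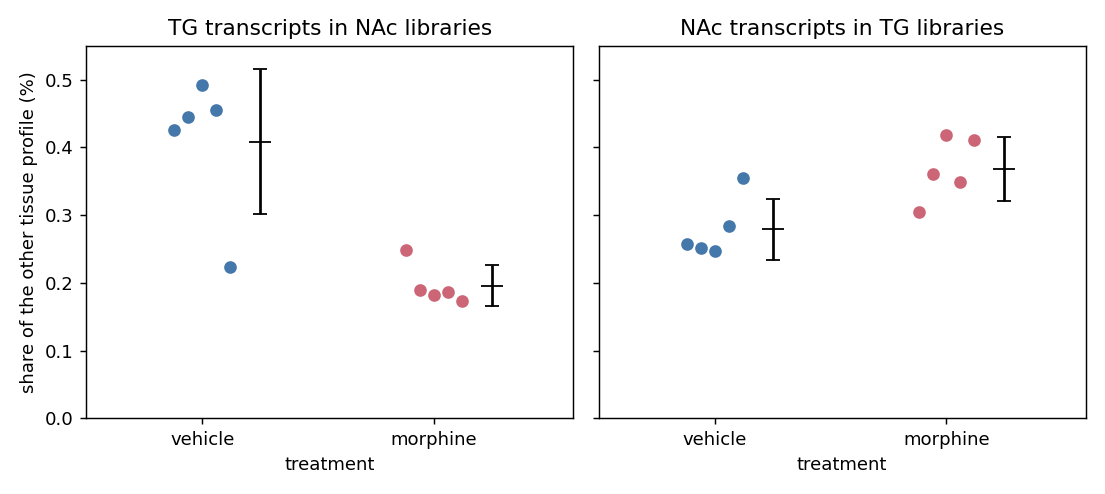
Points are libraries and bars the mean and SD of 5, for the share of each NAc library that looked like TG (left, 41 genes) and of each TG library that looked like NAc (right, 31 genes), in percent. TG transcripts made up 0.409% of vehicle and 0.196% of morphine NAc libraries, and NAc transcripts 0.279% of vehicle and 0.369% of morphine TG libraries.

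The genes with the smallest p in NAc were Prelp, an extracellular matrix protein gene (12.7 ± 0.872 CPM after vehicle and 8.15 ± 0.378 CPM after morphine, adjusted p = 0.0746), and Phgdh, the first enzyme of serine synthesis (55.6 ± 2.04 and 45.1 ± 0.437 CPM, adjusted p = 0.0995). Bcas1 (-0.37 ± 0.05), Serpinb1a (-0.59 ± 0.09) and the netrin receptor gene Unc5b (-0.43 ± 0.06) followed. In edgeR's quasi-likelihood test 0 of 29910 features passed, against 1709 at an unadjusted p under 0.05, 245 called by DESeq2 and 4 by limma voom. A fit on all 20 libraries, which takes its spread from both tissues, called 73. At this spread 34% of simulated genes changed 1.5-fold, all with a mean over 1 CPM, were recovered in NAc, so smaller changes were mostly not detectable. The simulated data gave 97 calls in all, which eases the Benjamini-Hochberg threshold, so with 0 real calls the share is likely lower than 34%.

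Other lists were called in NAc and lost with an estimated correlation. Heat shock genes had a mean log2 fold change of -0.29, with 11 of 11 negative (Hspa1a at -0.83 ± 0.23, Hspa1b at -0.89 ± 0.31), camera adjusted p = 2.38e-07 and adjusted p = 0.182 with an estimated correlation. Endothelial genes (-0.12, Cldn5 and Cdh5 lower adjusted over the list alone and 0 over all features) had adjusted p = 7.68e-06 and adjusted p = 0.411 with an estimated correlation. Cytosolic ribosomal protein genes (-0.04, 69 of 82 negative, with Rpl34 at -0.10 ± 0.04) had 4.59e-05 and adjusted p = 0.585 with an estimated correlation. MHC class I genes (-0.17, H2-Q4 and B2m) had 0.0021 and adjusted p = 0.543 with an estimated correlation, and their mean was -0.098, -0.099 and -0.085 without morphine replicate 2, 3 or 4. MHC class II genes (-0.25, Cd74 and H2-Ab1) had 0.0335 and adjusted p = 0.543 with an estimated correlation. Astrocyte genes (-0.13, Aqp4 and Gja1) had 0.00297 and adjusted p = 0.543 with an estimated correlation. Their mean was -0.079 without morphine replicate 3 and -0.022 without vehicle replicate 2. Shared medium spiny neuron genes (0.18, Foxp2 and Gad2) had 0.0122 and adjusted p = 0.585 with an estimated correlation. Their mean was 0.329 without vehicle replicate 5 and 0.031 without vehicle replicate 2. Red blood cell genes (0.25, Hba-a1 and Hbb-bt) had 0.0462 and adjusted p = 0.549 with an estimated correlation.

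Tissue next to the accumbens also differed between NAc libraries. Genes of septum, pallidum and hypothalamus had a mean of -0.36 (Oxt and Zic1; camera adjusted p = 0.0462, adjusted p = 0.585 with an estimated correlation). Without vehicle replicate 2, which held 17.0 CPM of the oxytocin gene Oxt, that mean was 0.015 (adjusted p = 0.787), and without that library the astrocyte and shared medium spiny neuron lists had adjusted p of 0.181 and 0.535. The septum list also lost its call without morphine replicate 3 or 4 (0.269 and 0.066), and the shared list without vehicle replicate 3 (0.137). The MHC class II call was lost without morphine replicate 3 or 4 or vehicle replicate 1, 2 or 5 (0.0715, 0.0901, 0.0941, 0.0851 and 0.191), and that of red blood cells without morphine replicate 3 or 4 or vehicle replicate 1, 2, 4 or 5 (0.329, 0.0923, 0.107, 0.138, 0.078 and 0.05). The list of cortical glutamatergic neurons had a mean of 0.80 and camera adjusted p = 0.0813, with the vesicular transporter gene Slc17a7, chosen after its values were seen, between 3.04 and 731 CPM among vehicle libraries.

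Opioid genes in NAc had values of both signs, 5 of 10 positive and 5 negative, and 0 passed in edgeR. Penk, the enkephalin precursor, averaged 47.8 ± 14.3 CPM after vehicle and 66.0 ± 9.13 CPM after morphine (SD, n = 5; log2 fold change 0.46 ± 0.20, edgeR adjusted p = 0.865), and the dynorphin precursor Pdyn 192 ± 42.3 and 243 ± 54.2 CPM (adjusted p = 0.943). The kappa receptor gene Oprk1 had a log2 fold change of 0.23 ± 0.10, Oprm1 of 0.18 ± 0.15 and Oprd1 of 0.11 ± 0.17. These are the 5 positive members of the opioid list, and the other 5 were negative. The opioid list (mean 0.06, adjusted p = 0.28), dopamine receptors and signalling (0.13, 0.28) and cAMP signalling (0.07, 0.265) were not called. Fkbp5 had 0.27 ± 0.07, and the metallothionein genes Mt1 and Mt2 -0.20 ± 0.04 and -0.26 ± 0.08. Together with Pdk4 (-0.25 ± 0.08) these made 1 glucocorticoid target higher and 3 lower adjusted over the list alone, against 0 over all features. The NMDA receptor gene Grin2a (1.03 ± 0.22) was 1 member of the GABA and glutamate receptor list past the threshold adjusted over the list alone.

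**Figure D3:**
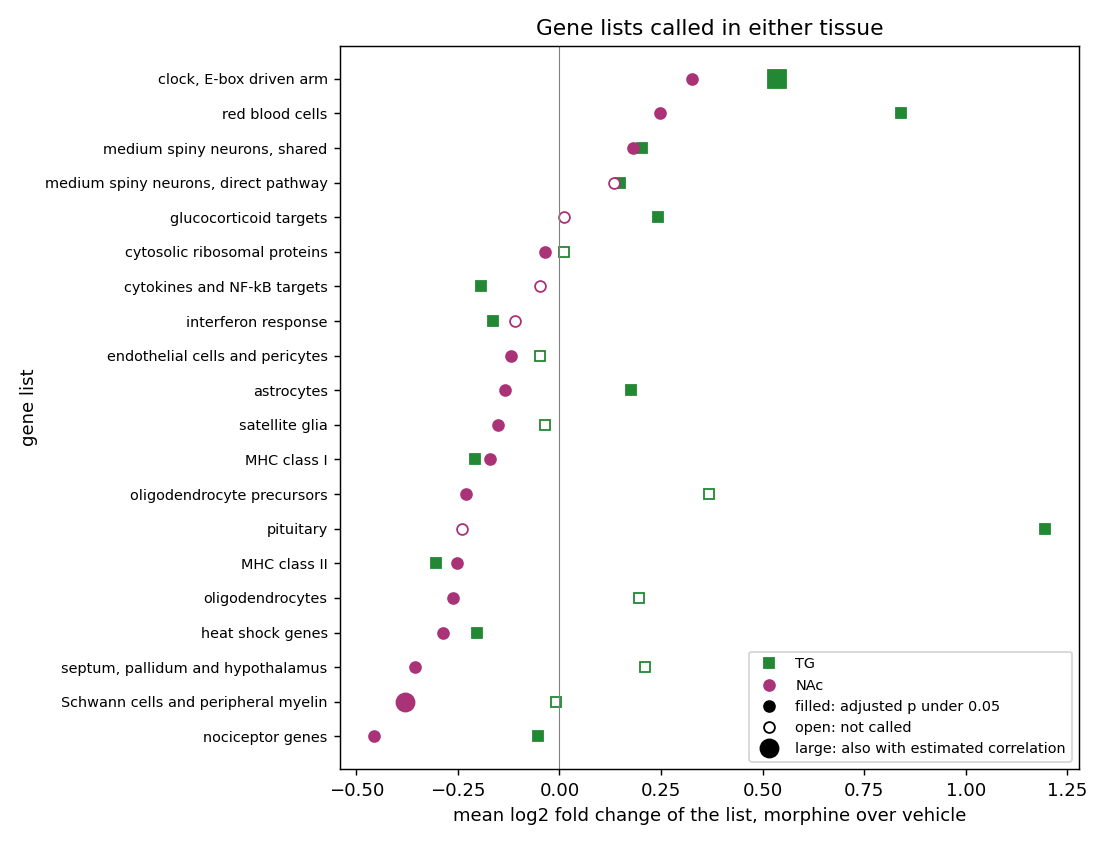
Mean log2 fold change (morphine over vehicle) of each gene list called by camera in TG (squares) or NAc (circles). Filled symbols mark lists called with the preset correlation, and large ones those also called with an estimated correlation, which were the E-box list in TG (0.535) and the Schwann cell list in NAc (-0.381).

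The response to morphine differed between the tissues for a few genes. Lnpep (gene 240028, chromosome 17, 17527723 to 17624489) averaged 14.0 ± 1.32 and 35.8 ± 8.25 CPM in TG of vehicle and morphine mice and 5.01 ± 0.452 and 4.56 ± 0.520 CPM in NAc (SD, n = 5), a difference between the effects of 1.49 ± 0.19 on the log2 scale. Zfp292 (1.89 ± 0.28) and Arfgef3 (0.62 ± 0.10) also had the larger effect in TG. For the integrin gene Itgb4 (0.52 ± 0.07), Serpinb1a (0.57 ± 0.08), Prelp (0.66 ± 0.10) and the myelin gene Pllp (0.50 ± 0.09) the mean in NAc was lower after morphine. The homeobox gene Tlx2 (2.44 ± 0.33), the glucose transport gene Trarg1 (1.38 ± 0.22) and the nociceptor channel regulator Pirt (1.02 ± 0.18) had nearly all their transcripts in TG, with 48.9 CPM of Tlx2 in TG and 0.148 CPM in NAc of vehicle mice. None of the E-box genes was among the calls; 9 of 12 had the larger estimate in TG, with a smallest edgeR adjusted p = 0.133.

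In edgeR's interaction test with Benjamini-Hochberg adjustment 13 of 32998 features passed, against 228 in DESeq2 and 0 in limma voom, 11 with the higher and 2 (Gm33320 and Gm33449) with the lower effect in TG, and the adjusted p of the genes above lay between 0.00896 and 0.0451. Next on the lower side came Ugt1a6a (-0.50 ± 0.10), Rnf168 (-0.19 ± 0.04), Atxn3 (-0.21 ± 0.04), Sat1 (-0.35 ± 0.07) and Hnrnpu (-0.16 ± 0.04), which did not pass. With the mouse as a block 1 feature passed (Gm33320, log2 difference -0.64, adjusted p = 0.0461). After subtraction of the other tissue's share 6 passed (Lnpep, Itgb4, Zfp292, Serpinb1a, Prelp and Gm33320), while Arfgef3 (0.62 before and after), Pllp (0.50), Aebp1 (1.04) and Gm33449 (-2.13 before and -2.15 after), the last 2 chosen after their values were seen, missed the threshold with adjusted p between 0.0568 and 0.0637. Tlx2 had 2.56 ± 1.15 and Trarg1 0.27 ± 1.07 after subtraction (adjusted p = 0.744 and 0.9999), and the standard error of Pirt went from 0.18 to 1.05 (adjusted p = 0.941). For Tlx2 and Pirt the subtraction left so few counts in NAc that the standard error grew. The standard error of Trarg1 also grew, from 0.22 to 1.07. The values of Tlx2, Pirt and Trarg1 after subtraction therefore cannot tell whether the difference would remain without the other tissue's share. Without NAc vehicle replicate 5 the count was 33, without NAc vehicle replicate 2 or 3 or TG morphine replicate 4 or 5 it was 8, and without NAc vehicle replicate 1 or 4, NAc morphine replicate 4 or 5, TG morphine replicate 1 or TG vehicle replicate 1 it was 7. It was 6 without NAc morphine replicate 2, TG morphine replicate 3 or TG vehicle replicate 3 or 5. Of the 10 named genes with each of 20 libraries left out, 65 of 200 calls were lost, those of Arfgef3, Pirt, Pllp and Trarg1, with adjusted p between 0.0501 and 0.16.

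Averaged over both tissues, the clock genes led the higher genes. Ciart (1.03 ± 0.08), Per3 (0.48 ± 0.04), Dbp (0.81 ± 0.08), Nr1d2 (0.27 ± 0.03) and Tef (0.32 ± 0.04) rose, and 8 of the 12 E-box genes passed. The collagen gene Col3a1 (-0.53 ± 0.07), Tlx2 (-1.24 ± 0.16), Serpinb1a (-0.31 ± 0.04), Sat1 (-0.25 ± 0.04) and Prelp (-0.31 ± 0.05) had a negative mean effect, which need not be a fall in each tissue. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 75 of 32998 features passed, 39 higher and 36 lower, with adjusted p of the 10 named genes between 3.58e-06 and 0.00859. This fit has no term for the mouse and takes the 2 libraries of a mouse as independent, so its p can be too small. Across all genes the deviations of a mouse in TG and NAc had correlations between -0.098 and 0.095, which does not settle this for single genes. Tlx2, Serpinb1a and Prelp also had a different effect in the 2 tissues, and their estimated fall lay in NAc. In NAc alone Serpinb1a was at -0.59 ± 0.09 and Prelp at -0.64 ± 0.07, about the size of their interactions (0.57 and 0.66). Sat1 was at -0.43 ± 0.05 in TG alone, more than its mean over both. Tlx2 did not pass after subtraction of the other tissue's share (-1.30 ± 0.58, adjusted p = 0.548), which left hardly any of its counts in NAc. The count was 121 without NAc vehicle replicate 5, 45 and 37 without TG morphine replicate 2 or 5, 48 and 46 without TG vehicle replicate 1 or 3, 49 without NAc morphine replicate 2 and 47 without NAc vehicle replicate 3.

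The same mice gave both tissues, so differences between mice can enter both comparisons. Of 18096 named genes measured in both, 169 had an unadjusted p under 0.05 in both tissues. Among them, 125 (74.0%) went the same way, 45 higher and 80 lower. The 95% Clopper-Pearson interval of this share was 66.7% to 80.4% if genes were independent, which they are not. If the tissues were independent, 64.5 genes would be in both and go the same way, to be set against the 125. Splits of the mice that ignore treatment had a median share of 58.8% with the same direction, and 13 of 99 had a share at least as high as 74.0%, so the share alone says nothing about morphine. Across genes the log2 fold changes had Pearson's r = 0.056 and Spearman's rho = 0.081, and genes are not independent replicates. Of the 45 named genes called in TG, 44 were measured in NAc and 30 had the same direction there, 8 with an unadjusted p under 0.05. Without the E-box genes 22 of 36 had the same direction.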

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

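The tests of the hours of collection, of depth in NAc, of isoform models, of Lnpep, Zfp292 and Arfgef3 in TG alone, of GC content and length for the long genes, and of the order of replicate numbers were chosen after the result was seen.

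In TG and NAc the E-box driven clock genes were higher after morphine, with mean edgeR log2 fold changes of 0.533 and 0.323, and only the real split, 1 of 100, reached these values, with 0.377 and 0.292 the highest others. Chance is unlikely on this count, but in NAc the margin is small and leans on single libraries (camera mean 0.327 with all, 0.275 without vehicle replicate 2 and 0.281 without morphine replicate 3), and the list's camera adjusted p there was 0.137 with an estimated correlation. The mean in TG was 0.537 after correction for GC content and length and 0.547 with the pituitary score as a covariate, which argues against either as the whole cause. All 12 members were positive in NAc of the same mice, as a difference in the hour of tissue collection between treatments would also give, and the labels give no hour, so this and an effect of morphine or its withdrawal on the clock cannot be told apart. In TG Per1 fell with the replicate number in both treatments (mean rank correlation -0.95, exact permutation p = 0.00125, adjusted p = 0.03 over 12 genes in 2 tissues, where no other passed), which may reflect an order of collection shared by the treatments, and a shifted rhythm and a change in level stay open as well.

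Genes abundant in TG, peripheral myelin and oligodendrocytes were lower in NAc after morphine. A lower share of TG RNA or reads in the morphine NAc libraries may account for part of the TG genes: across 144 genes 20 to 200 times higher in TG, none used to estimate the share, the slope of observed on expected log2 fold change was 1.042 ± 0.225, and 133 of the 144 were lower. The median observed change was -0.323 against -0.126 expected, so part of the fall is left over, and library totals argue against depth, with a morphine to vehicle ratio of 1.08 and an exact permutation p of 0.143. For oligodendrocytes the tables argue against the share as the cause: their mean was -0.267 after subtraction and -0.241 with a cortical score against -0.265 without. Lnpep, Zfp292 and Arfgef3, picked from the interaction calls, had a median of 1.35 in the TG libraries alone against a median interaction of 1.488, both the values of Lnpep. Zfp292 rose by 1.62 in TG against an interaction of 1.89. Reads in NAc libraries cannot alter TG libraries, which argues against the share for Lnpep and Zfp292. For Arfgef3 this median cannot tell. Its interaction was 0.624 ± 0.105 before and 0.625 ± 0.105 after subtraction of the share, which argues against the share for Arfgef3 as well. After subtraction it missed the threshold in edgeR's interaction test (adjusted p = 0.0568). Whether fewer oligodendrocyte transcripts reflect morphine, a different amount of white matter in the pieces, or another feature of the dissection was not tested.

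Genes called higher in TG were long and AT-rich: outside the E-box list, 22 of the 28 with a value were longer and 24 had lower GC than the median gene, with a median length of 9338 against 3179 bases and a median GC of 43.26% against 49.55%. After correction for GC content and length the median log2 fold change of these 30 genes was 0.308 against 0.327, and 25 still passed, which argues against a smooth trend in either as the whole cause. Reads moved between isoform models stay open: at an unadjusted p under 0.001, 13 unmatched transcripts were lower and 20 higher, against 126 named genes higher and 45 lower, and these counts cannot tell. Longer or less degraded RNA in the morphine ganglia is a possible explanation that could not be measured from counts. No biological explanation for gene length was tested.

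Other splits of the 10 mice were tried for each treatment count, 100 of the 126 possible. In TG 1 of 100, the real one, gave as many as 53 genes, and the highest other gave 3, so chance is unlikely. The smallest share that 100 splits can reach is 1 of 100, and several counts were tested in this way. In NAc the real split gave 0 genes and the highest other 1, and all 100 gave as many, which a count of 0 fixes in advance and which says nothing. At an unadjusted p under 0.05 the real split gave 1709 genes, the highest other 3151, and 17 of 100 as many, so chance cannot be excluded for that count. For the interaction the real split gave 13 and the highest other 7, for the mean over both tissues 75 and 10, and for the number of genes at an unadjusted p under 0.05 in both tissues and in the same direction 125 and 70, each reached by 1 of 100, so chance is unlikely for these 3 counts. The margin was smallest for the interaction, whose count was 0 in limma voom, 1 with the mouse as a block and 6 after subtraction of the other tissue's share. For the tissue difference the 10 vehicle libraries were split: the real split gave 22232 genes and the highest other 7903, and 1 of 100 gave as many, so chance is unlikely. Of these, 11 splits part the libraries of all 5 mice as the real one does, too few for a share under 0.05 by themselves, and the highest of those that part 3 mice or 1 were 6950 and 1.

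In 23 of 316 groups of 5 libraries 1 library stood apart, with a gap to the nearest other of more than 0.71 of the range, where chance gives 15.8 groups, or 1 in 20. Of the 23, 22 are given here. The share of TG transcripts was 0.249% in NAc morphine replicate 1 against 0.173% to 0.19% in the others (gap over range 0.776). It was 0.223% in NAc vehicle replicate 5 against 0.426% to 0.493% (0.752), and Prph in the same library was 1.34 CPM against 3.39 to 3.99 (0.773). The MHC class I score of that library was 2.90 against 3.02 to 3.06 in mean log2 of CPM + 1 (0.758). NAc vehicle replicate 2 had an E-box score of 6.30 against 6.54 to 6.58 (0.852) and a septum, pallidum and hypothalamus score of 3.81 against 2.14 to 2.41 (0.838). It also held 17.0 CPM of Oxt against 0.653 to 1.14 (0.97) and 118 CPM of Olig1 against 82.8 to 87.6 (0.864). Prelp was 14.2 CPM in NAc vehicle replicate 4 against 12.0 to 12.6 (0.742), and Per3 79.0 CPM in NAc vehicle replicate 1 against 66.1 to 68.9 (0.785). In NAc morphine replicate 1 Grin2a was 1.75 CPM against 1.04 to 1.18 (0.806) and Avil 2.50 CPM against 1.53 to 1.81 (0.711). Pou4f1 was 0.509 CPM in NAc morphine replicate 3 against 0.337 to 0.367 (0.825).

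In TG vehicle replicate 2 Fabp7 was 171 CPM against 187 to 194 (0.724) and Ifi27 79.6 CPM against 85.1 to 87.3 (0.72). TG morphine replicate 4 had 266 CPM of Akap11 against 284 to 289 (0.803) and 243 CPM of Dmxl2 against 261 to 265 (0.796). TG morphine replicate 3 had 9.26 CPM of Slc4a1 against 0.603 to 2.87 (0.738). Hsph1 was 277 CPM in TG vehicle replicate 3 against 240 to 244 (0.874), and Drd1 1.02 CPM in TG vehicle replicate 4 against 0.582 to 0.686 (0.767). Chgb was 230 CPM in TG vehicle replicate 5 against 205 to 211 (0.776), and Oprk1 9.21 CPM in TG morphine replicate 2 against 7.39 to 7.87 (0.736).

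The test of the difference between the tissues picked out 13 genes, as effect in TG minus effect in NAc in log2. Higher in TG were Lnpep by 1.488, Zfp292 by 1.889 and Arfgef3 by 0.624. The genes Tlx2 with 2.441, Trarg1 with 1.378 and Pirt with 1.024 are those with hardly any transcripts in NAc. Itgb4 with 0.519, Serpinb1a with 0.567, Prelp with 0.658, Pllp with 0.502 and Aebp1 with 1.039, the last beyond the rule for named genes, completed the higher side. Gm33320 with -0.643 and Gm33449 with -2.134, chosen after their values were seen, were lower.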

How the results depend on the processing

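Named genes alone, the GC and length correction, the covariates and the subtraction of the other tissue's share were chosen after the data had been seen; the other alternatives were planned. In TG the count of 53 was 148 at an adjusted p of 0.1, 709 in DESeq2, 81 in limma voom, 85 with a mean of at least 1 CPM, 32 for single transcripts, 122 among named genes alone and 12 with the pituitary covariate. With that covariate the median size of the log2 fold change of the 53 was 0.387 against 0.427, and the covariate takes 1 degree of freedom. A fit on all 20 libraries called 62 in TG, a similar count, but only 27 of these were among the 53. In NAc the count of 0 was 2 at an adjusted p of 0.1 (Prelp, Phgdh), 245 in DESeq2, 4 in limma voom (Nr1d2, Phgdh, Prelp and 1 unmatched transcript), 1 with a mean of at least 1 CPM (Prelp), 73 with all 20 libraries in 1 fit, 3 among named genes alone (Ciart, Phgdh, Prelp) and 1 with the cortical covariate (Pmp22). The mean over both tissues gave 75, and 170 at an adjusted p of 0.1, 574 in DESeq2, 150 in limma voom and 33 for single transcripts. The interaction gave 13, and 8 with library size only, 228 in DESeq2, 0 in limma voom, where 2830 had an unadjusted p under 0.05, 8 with no low count filter and 6 with the other tissue's share subtracted. Looser or stricter thresholds and fewer features tested act by construction; for the other alternatives the cause was not tested.

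Leaving out 1 library at a time gave 21 to 77 genes in TG, 0 in NAc, 6 to 33 for the interaction, 21698 to 22409 for the tissue difference, 37 to 121 for the mean effect and 65.79% to 81.77% for the share of genes with 1 direction in both tissues. The septum, pallidum and hypothalamus list in NAc had a mean between -0.49 and 0.015, the highest without vehicle replicate 2, which reversed it. Of the 18 named genes called in TG, 13 kept their call with each library left out and 39 of 180 such calls were lost. Under the other settings 34 of 216 calls were lost, from 17 of the 18 genes. Only 1 gene (Per3) kept its call in all of these settings, and no sign reversed. The 14 genes of the tissue comparison kept their calls in all settings, and the 10 of the mean effect lost 3 of 80 outside leave-one-out. Of the called lists, 9 of 13 in TG and 10 of 15 in NAc kept their call with each library left out. Under all the other settings, the estimated correlation included, 1 of 13 in TG and 1 of 15 in NAc kept it.

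Replicate numbers within a tissue name different mice. Same-numbered libraries had correlations of -0.214 to 0.137 in TG, where 0 of 5 were closest to their own number. In NAc they were 0.095 to 0.678, with 4 of 5 over 0.1 and 2 of 5 closest to their own number, a hint of pairing from the data that the labels do not state. The numbers were not taken as pairs, since not every correlation was over 0.1. The replicate number as a block left 2 genes (Per2, Per3) in TG and 0 in NAc, gave 57 for the mean effect, and ended the call of the MHC class II list in NAc (adjusted p = 0.0587). With the mouse as a block across tissues the interaction kept 1 gene and the tissue difference had 21406. The mouse block ended the calls of the named interaction genes. Over all settings tried, this block included, the smallest difference was 1.389 for Lnpep, 0.472 for Itgb4 and 0.613 for Prelp, against 1.488, 0.519 and 0.658 in the main fit. That of Trarg1 went from 1.378 ± 0.219 to 0.269 ± 1.072 with the other tissue's share subtracted. This standard error is too large to tell whether the difference remained.

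In simulated NAc data 6% of the genes with the smallest change, all with a mean over 1 CPM, were recovered, so changes of that size were mostly not detectable.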

Other observations

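More genes passed for the mean effect over both tissues than were named for it above; those given here were chosen after their values were seen, and no list was tested for this effect. Cd93 (log2 fold change -0.32), Cldn5 (-0.34), Plat (-0.20), Vegfa (-0.14) and Slc16a1 (-0.19) fell, and Fkbp5 (0.27), Plin4 (0.82) and Fam107a (0.35) rose. All passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, in the fit that has no term for the mouse. Bhlhe41 (0.25) and Nr1d1 (0.34) were among the 8 E-box genes that passed.

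Immediate early genes, which follow recent neuronal activity, had a mean log2 fold change of 0.19 in NAc (18 of 20 positive, camera adjusted p = 0.0593) and -0.03 in TG (14 of 20 negative, adjusted p = 0.0642), and neither list was called. Nuclear genes of oxidative phosphorylation had means of 0.01 in TG and -0.01 in NAc over 81 members, with adjusted p of 0.695 and 0.618.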
